A study of Mus musculus with 4 samples.

How the data were processed

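The series held 4 single-cell RNA libraries from KPC46 mouse pancreatic tumours, 2 from mice given vehicle and 2 from mice given TAK-981, an inhibitor of the SUMO-activating enzyme. Each library came from 1 mouse, and the mouse was the unit of replication throughout. The deposited values were unique molecular identifier (UMI) counts per gene and cell barcode, made by the authors with Cell Ranger 6.1.2 against mm10 per the submitters' processing notes and the file headers. The libraries were 10x 3' v3.1 per the labels. Reads were not mapped again here. The samples, the comparison, the quality limits, the marker lists, the 52 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Further alternatives, among them the fits without transcripts shorter than 800 nt and with the length trend removed, were chosen after the data had been seen. No deposited count column was left unused, so columns not used numbered 0.

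Barcodes numbered 5556 and 4596 in the vehicle libraries and 2872 and 3866 in the TAK-981 libraries. Total UMIs per library were 24411656, 29041348, 26376608 and 63898760 in the same order. Barcodes with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs were kept, which left 4576, 4276, 2255 and 3191. Scrublet scores were computed per library, and barcodes at the top of the score distribution were removed at an assumed rate of 0.8% per 1000 cells, giving 168, 146, 41 and 81 removed barcodes. The cells analysed were 4408, 4130, 2214 and 3110, with median depths of 2269, 4148, 5024.5 and 12831 UMIs. The replicate libraries were checked for identity, and the counts of the same genes differed between libraries of 1 group by far more than sampling noise, with chi-squared per degree of freedom of 189 for vehicle and 127 for TAK-981.

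Counts were scaled to 10000 per cell and log transformed with scanpy 1.11.5 in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, matplotlib 3.10.9). Clustering used 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0 and seed 0, without integration of libraries. Clusters were named from fixed marker lists by mean marker score. A name was given only when at least 3 of the list's markers were each found in at least 10% of the cluster's cells, and a cluster stayed unnamed when it met no list, when its top 10 genes held more markers of another list, or when it had few UMIs and no marker among them. The T or NK cells were clustered again by the same steps to name subclasses. Named clusters were treated as resembling the cell type of the marker list, since no protein marker was measured.

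Counts were summed per library and class, and classes with at least 30 cells in every library were compared (epithelial, macrophage or monocyte, fibroblast, T or NK and neutrophil). Dendritic and endothelial cells were added later with a limit of 15 cells. Genes were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3 (limma 3.58.1, data.table version 1.17.8), with low counts filtered, TMM scaling and Benjamini-Hochberg adjustment over all genes tested in a class at 0.05. Values per library are given as CPM, the UMIs of a gene scaled to the TMM-adjusted total of the class in that library. Fold changes are log2 of TAK-981 over vehicle with standard errors (SE) from the fit. The edgeR p-values rest on the spread of n = 2 mice per group, and those of gene lists at a preset correlation hold little of it.

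Gene lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and adjusted by Benjamini-Hochberg over all classes and lists. The same lists were tested with camera at a correlation estimated from the data and with fry. The lists covered interferon and antigen presentation, lymphocyte and myeloid states, fibroblast states, tumour programmes, stress, metabolism, SUMO genes and markers of other cell types. Each list also received a count of member genes passing over all genes and a count passing when adjusted over the list alone. Genes were named when the adjusted p was below 0.05, mean log2 CPM was at least 5 and the libraries did not overlap, ranked by fold change, with 12 per direction in epithelial cells, macrophages and fibroblasts and 5 per direction in other classes. Up to 4 members of each called list and genes of the SUMO pathway were added, and some genes and a list were not used here. Immunoglobulin and T cell receptor segments, haemoglobin, mitochondrial, X-inactivation and Y genes were left out of the ranking. A gene with no counts in 1 group was given a bound from a floor of 3 counts.

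Intervals of shares are exact (Clopper-Pearson) binomial intervals at 95%, and these intervals and floors cover counting error only. Intervals of medians over genes are at 95% from bootstrap draws of genes and carry no spread between tumours. Class shares were compared with an exact two-sided permutation test of the 4 libraries, which cannot give a p below 0.333 with 2 against 2, and class cell numbers with edgeR. Alternatives covered doublet removal, limits of mitochondrial and UMI content, clustering resolution, naming, gene filtering, DESeq2 1.42.0 and genes from other cells left out. They also covered leaving out each library, the 2 fits for transcript length and thinning of UMIs to an equal median depth of macrophages. That thinning did not match the depth of the other classes. Transcript lengths, gene identifiers and coordinates came from GENCODE vM21 on GRCm38, which matched 22331 of 22344 genes. Highest class and share of highest compare the mean CPM of a gene between classes.

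The gene test was tested on simulated data with the means, depths and dispersions of each class, in which 100 genes were changed 2-fold and 100 genes 4-fold. It recovered 9, 15, 9, 3 and 3% of the 2-fold changes and 68, 75, 76, 68 and 36% of the 4-fold changes in epithelial, macrophage, fibroblast, T or NK cells and neutrophils. False calls in the same order numbered 5, 11, 13, 4 and 1, or 6.1, 10.9, 13.3, 5.3 and 2.5% of calls. In a simulation that raised oxidative phosphorylation genes 2-fold, that list was called in all 5 classes, and 3, 1, 0, 0 and 0 other lists were called. It used camera at the preset correlation, with genes drawn independently of each other. Camera at an estimated correlation and fry were not run on it.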

Results

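The 4 tumours gave 4408 and 4130 cells in the vehicle libraries and 2214 and 3110 cells in the TAK-981 libraries. The comparison asks how an inhibitor of SUMOylation changes the cells of a pancreatic tumour and their gene expression. KPC46 is a mouse pancreatic tumour organoid line grown here as a tumour in B6/129 F1J mice. Macrophages had median depths of 2798 and 3119 UMIs in vehicle and 5147 and 7524 UMIs in TAK-981 libraries, so depth differed between the groups. The median mitochondrial share of UMIs per cell was 2.93 and 2.71% in vehicle and 6.90 and 5.11% under TAK-981. Neither the labels nor the processing notes name a batch, and any batch that followed the groups cannot be told apart from treatment.

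Neutrophil-like cells made up 12.1 and 9.10% of cells in the vehicle tumours and 1.72 and 1.25% in the TAK-981 tumours. Their mean share was 10.6% ± 2.15 (SD, n = 2) in vehicle and 1.49% ± 0.327 (SD, n = 2) under TAK-981, 7.15-fold lower, with an exact two-sided permutation p of 0.333, the smallest that 2 against 2 tumours can give. Among immune cells the neutrophil share was 24.9% ± 7.98 in vehicle and 4.54% ± 0.550 under TAK-981 (SD, n = 2, exact permutation p = 0.333). Macrophage-like cells took 55.2% ± 6.79 of immune cells in vehicle and 77.9% ± 7.41 under TAK-981 (SD, n = 2, exact permutation p = 0.333). With at least 1000 UMIs per cell they were 1250 of 1904 and 653 of 800 immune cells in vehicle. Under TAK-981 they were then 522 of 662 and 467 of 735, so the groups overlapped. T or NK-like cells took 5.63% ± 0.144 of immune cells in vehicle and 13% ± 7.72 under TAK-981 (SD, n = 2, exact permutation p = 0.333), where TAK-981 1 and TAK-981 2 had 7.54 and 18.5%. Their difference of 7.37 percentage points was 1.91 without TAK-981 2 and 12.8 without TAK-981 1. The edgeR quasi-likelihood test on cell numbers called 0 of the classes, and neutrophils had a log2 ratio of -2.84, an unadjusted p of 0.0496 and a Benjamini-Hochberg adjusted p of 0.312. The median depth of neutrophils was 659 and 621 UMIs in vehicle against 1615.5 and 1465 UMIs under TAK-981. With at least 1000 UMIs per cell the neutrophil-like cells numbered 89 and 75 in vehicle and 40 and 103 under TAK-981, in place of 535, 376, 38 and 39, and the difference was 0.450 percentage points in place of -9.14. That setting removed vehicle cells and also named more cells of TAK-981 2. Best-scoring names alone gave -11.5, so naming alone did not remove the difference. The other settings of cells and clusters gave differences from -11.5 to -8.26.

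Epithelial-like cells were 35.3% ± 17.9 of all cells in vehicle and 53.1% ± 12.4 under TAK-981 (SD, n = 2, exact permutation p = 0.667). The difference of 17.8 percentage points was 0.689 without doublet removal, 8.77 at 1000 UMIs per cell, 5.14 without vehicle 1, 30.4 without vehicle 2 and 8.98 without TAK-981 2. Macrophage-like cells were 24.8% ± 9.79 and 26.4% ± 11.2 of all cells (SD, n = 2, exact permutation p = 0.667), and fibroblast-like cells were 3.99% ± 2.27 and 3.40% ± 0.117 (SD, n = 2, exact permutation p = 1.0). T or NK-like cells were 2.63% ± 1.39 in vehicle and 3.91% ± 1.12 under TAK-981 (SD, n = 2, exact permutation p = 0.667). That difference of 1.28 percentage points was 0.298 without vehicle 2 and 0.49 without TAK-981 2. The macrophage-like difference turned negative without vehicle 2 (-5.29) and without TAK-981 1 (-6.30), and the fibroblast-like difference turned positive without vehicle 2 (1.01). The macrophage-like difference was also negative at 10% mitochondrial UMIs and at 1000 UMIs per cell. B-like cells made up 9.73% of vehicle 1 but 0.339% of vehicle 2, and 0.407 and 0.096% of the TAK-981 libraries, so vehicle 1 alone set the vehicle mean. Acinar-like cells were 0.340% of vehicle 1 and 0 of 4130 cells of vehicle 2, against 7.72 and 1.32% of the TAK-981 libraries (exact permutation p = 0.333). The count of 0 allows a share of up to 0.073% by a floor of 3 cells and 0.089% by the exact 95% interval. The acinar difference of 4.35 percentage points was 1.15 without TAK-981 1 and 7.55 without TAK-981 2. All 227 acinar-like cells lay in a cluster with Malat1 in 44.05% of cells and a median of 1301 UMIs. Plasma-like cells were 30 of 4408 cells in vehicle 1, 0 of 4130 in vehicle 2, 0 of 2214 in TAK-981 1 and 1 of 3110 in TAK-981 2, and erythroid-like cells were found in vehicle 1 alone (14 cells). Dendritic-like cells were 2.94% ± 3.00 and 1.29% ± 0.60, and endothelial-like cells were 1.79% ± 0.546 and 1.14% ± 0.882 (SD, n = 2). These differences became 0.469 for dendritic-like cells without vehicle 1 and -0.031 for endothelial-like cells without TAK-981 2. Cells of clusters without a name were 12.2% ± 3.21 in vehicle and 4.46% ± 4.33 under TAK-981 (SD, n = 2, exact permutation p = 0.333). Without doublet removal they were 293 of 4576 and 96 of 4276 in vehicle against 454 of 2255 and 278 of 3191 under TAK-981. That is the opposite direction, and the difference in mean share was also positive at 10% mitochondrial UMIs.

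**Figure D1:**
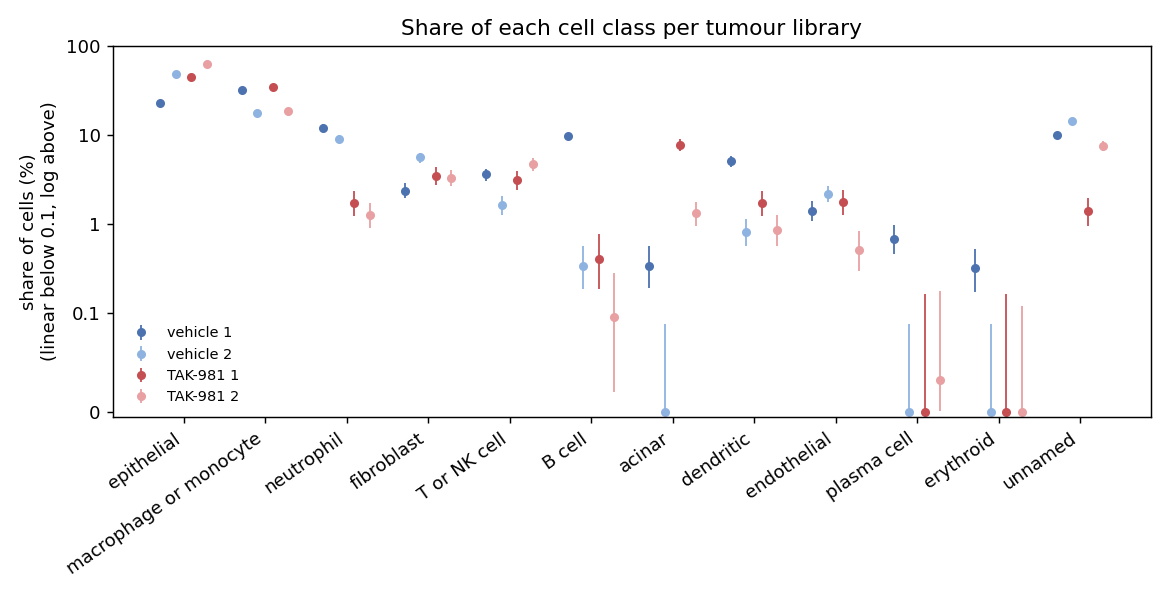
Share of cells (percent, axis linear below 0.1 and logarithmic above) of each cell class in the 4 tumour libraries, with exact 95% binomial intervals. The neutrophil points of both vehicle libraries (12.1 and 9.10%) lie above those of both TAK-981 libraries (1.72 and 1.25%).

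Cd8a RNA rose in the T or NK-like cells under TAK-981, and the cells named CD8-like were few in every tumour. The CD8-like cluster had a median of 6460 UMIs per cell and was led by cell cycle genes such as Mki67, Pclaf and Birc5, with 0 CD8 markers among its top 10 genes. It held 2 and 2 cells in vehicle and 6 and 9 under TAK-981, or 2.10% ± 1.19 and 7.43% ± 1.79 of T or NK-like cells (SD, n = 2, exact permutation p = 0.333). Cells with a UMI of Cd8a or Cd8b1 were 10.1 and 7.35% in vehicle and 21.7 and 20.5% under TAK-981 at median depths of 1220, 1114, 3304 and 2611 UMIs. At an equal depth of 500 UMIs these shares were 7.55, 2.94, 8.70 and 6.85% and overlapped between the groups. Macrophages, which should lack both genes, had shares of 0 (of 1398 cells), 0 (of 738 cells), 0.131 and 0.348% at full depth. CD4-like cells were 30.1% ± 7.23 of T or NK-like cells in vehicle and 50.2% ± 5.47 under TAK-981, and NK-like cells were 17.4% ± 10.1 and 6.02% ± 1.73 (SD, n = 2, exact permutation p = 0.333 for each). The CD4-like difference of 20.1 percentage points was -3.11 at 1000 UMIs per cell, 0.518 at 10% mitochondrial UMIs and 9.61 with thinned libraries. The NK-like difference of -11.4 was -4.27 without vehicle 1 and -18.5 without vehicle 2. Regulatory T-like cells were 25.8 and 13.2% in vehicle and 0 of 69 and 0 of 146 cells under TAK-981. These counts of 0 allow up to 4.35 and 2.06% by a floor of 3 cells and 5.206 and 2.495% by the exact 95% intervals.

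The subclass shares rested on clusters that followed the groups. Foxp3 UMIs were found in 13.2 and 5.88% of T or NK-like cells in vehicle and in 10.1 and 14.4% under TAK-981, against 0 (of 1398), 0 (of 738), 0.131 and 0 (of 575) percent of macrophages. At an equal depth of 500 UMIs the Foxp3 shares were 6.29 and 2.94% in vehicle and 2.90 and 1.37% under TAK-981, of 159, 68, 69 and 146 cells. These shares did not overlap between the groups, but vehicle 2 and TAK-981 1 were nearly equal. The order thus rested on few cells, and at full depth the shares overlapped. The edgeR test on cell numbers gave regulatory T-like cells an adjusted p of 0.00102, with 0 TAK-981 cells and so no estimate of the ratio. The difference in regulatory T-like share was -14.3 to -24.99 percentage points without doublet removal, at 10% mitochondrial UMIs, at 1000 UMIs per cell, at Leiden resolution 2.0 and with interferon and MHC genes left out of clustering. With libraries thinned to equal macrophage depth the difference was 4.75 percentage points, opposite in direction, from 44 and 12 vehicle cells and 18 and 35 TAK-981 cells. A cluster left without a name, whose best marker score was that of regulatory T cells, held 1 and 1 vehicle cells against 22 and 37 TAK-981 cells. The CD8-like difference also changed direction without doublet removal (-5.81 percentage points) and with at least 1000 UMIs per cell (-12.2 percentage points).

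In epithelial-like cells Irf7, Trim30a and Gdf15 rose under TAK-981 in every fit in which they were tested, leave-one-out fits included. Irf7 had 1.71 and 0.839 CPM in vehicle and 16.0 and 10.2 CPM under TAK-981 (log2 fold change 3.39 ± 0.45 SE, n = 2, edgeR adjusted p = 0.0164), a level 0.0303 times that in neutrophils. Trim30a rose from 0.512 and 0.168 CPM to 5.70 and 5.73 CPM (4.14 ± 0.60 SE, n = 2, edgeR adjusted p = 0.0200). The p53 target Gdf15 rose from 0.768 and 0.112 CPM to 24.98 and 31.6 CPM (6.17 ± 0.64 SE, n = 2, edgeR adjusted p = 0.0124). Prl, the prolactin gene, had 112 and 190.4 CPM in vehicle and 0 and 0.773 CPM under TAK-981 (-8.24 ± 1.07 SE, n = 2, edgeR adjusted p = 0.0441), and its call was lost without vehicle 1 (adjusted p = 0.238) and without vehicle 2 (adjusted p = 0.292). These genes lie on GRCm38 with GENCODE vM21 coordinates: Irf7 (ENSMUSG00000025498) on chromosome 7 from 141262706 to 141266481, Trim30a (ENSMUSG00000030921) on chromosome 7 from 104409025 to 104465193, Gdf15 (ENSMUSG00000038508) on chromosome 8 from 70629393 to 70632456 and Prl (ENSMUSG00000021342) on chromosome 13 from 27057570 to 27065205.

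The type I interferon list was higher in epithelial-like cells, with a median log2 fold change of 1.68 over 37 genes (camera adjusted p = 6.35e-11, adjusted p = 0.849 with an estimated correlation). Of these genes 3 rose, 0 fell and the others did not pass over all genes tested, and 18 rose when adjusted over the list alone. Usp18 was the other riser (1.46 ± 0.29 SE, adjusted p = 0.0479). Interferon-gamma response genes had a median of 1.62 over 21 genes (camera adjusted p = 1.40e-07, 0.849 with an estimated correlation), with Irf8 (4.00 ± 0.63 SE, adjusted p = 0.0266) and Gbp3 (4.07 ± 0.72 SE, adjusted p = 0.0378) passing over all genes and 13 rising when adjusted over the list alone. MHC class I genes had a median of 0.90 over 22 genes (camera adjusted p = 1.62e-06, 0.849 with an estimated correlation), with 1 rising over all genes and 13 adjusted over the list alone. That gene, H2-D1, had 100.1 and 82.9 CPM in vehicle and 342 and 210 CPM under TAK-981 (1.59 ± 0.29 SE, adjusted p = 0.0426). Its call was lost without vehicle 1 (0.0836), vehicle 2 (0.150) and TAK-981 1 (0.117). Without TAK-981 1 the type I interferon median was 1.06. The calls of Gbp3 and Ifnar2 were lost without vehicle 2 and without TAK-981 1, and that of Usp18 whichever library was left out. Macrophage RNA made up an estimated 0.174 and 0.123% of epithelial RNA in vehicle but 2.13 and 0.254% under TAK-981, and without genes that other cells could supply the medians were 0.77, 0.81 and 0.46 for the 3 lists.

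Epithelial genes outside the interferon lists that rose included P3h4 (2.06 ± 0.23 SE, edgeR adjusted p = 0.0116), Fxyd5 (1.81 ± 0.23 SE, adjusted p = 0.0138), Vasp (1.38 ± 0.21 SE, adjusted p = 0.0248) and the complement gene Cfb. Cfb rose from 16.6 and 9.68 CPM to 116.4 and 53.5 CPM (2.70 ± 0.48 SE, adjusted p = 0.0497), a call lost without vehicle 1 (0.107) and without vehicle 2 (0.202). Ifnar2, a receptor chain for type I interferon, rose by 1.47 ± 0.28 SE (adjusted p = 0.0462). Lists of unfolded protein response (median 0.51, adjusted p = 0.00682), heat shock (0.66, 0.0207) and p53 target genes (0.20, 0.0314) were called upwards, each with an adjusted p of 0.849 at an estimated correlation. Over all genes 1 of the 19 p53 targets rose, Gdf15, and 0 of the 19 unfolded protein and 0 of the 15 heat shock genes passed. Chemokines had a median of 1.49 over 20 genes (adjusted p = 5.12e-06, 0.849 with an estimated correlation), where Ccl3 rose (2.48 ± 0.40 SE, adjusted p = 0.0285) from 2.39 and 1.46 CPM, 0.00463 times its neutrophil level. Neutrophil RNA made up an estimated 0.029 and 0.03% of epithelial RNA in vehicle and 0.333 and 0.093% under TAK-981. The call of Vasp was lost whichever library was left out and that of Ccl3 without vehicle 2 and without TAK-981 1. Without TAK-981 2 the unfolded protein (0.18), heat shock (0.31) and p53 lists (0.07) were not called, nor was heat shock without vehicle 2 (0.28), and the p53 median was 0.36 without vehicle 1. The chemokine median was 0.73 without TAK-981 1, 2.34 without vehicle 1 and 2.43 without TAK-981 2.

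Lists of genes typical of immune or stromal cells were also higher in epithelial-like cells, beside markers of those cells. MHC class II (median 2.68 over 7 genes, adjusted p = 0.0359), inflammatory macrophage (2.01 over 12, 0.000214), lipid-associated macrophage (0.63 over 17, 0.00249) and monocyte genes (1.43 over 14, 0.0149) had 0 genes passing over all genes, against 2661 epithelial genes at an unadjusted p under 0.05 and 1274 called by DESeq2. Adjusted over the list alone, 2 lipid-associated genes rose. T cell effector (2.10 over 6, 0.00649), neutrophil activation (1.79 over 15, 5.36e-05) and inflammatory fibroblast genes (1.43 over 16, 0.00304) were called as well, with Ccl3 the gene that passed in the T cell and neutrophil lists. Macrophage markers (3.48 over 8, adjusted p = 0.000807), acinar markers (3.26 over 12, 1.83e-05) and neutrophil markers (1.35 over 6, 0.00498) were called upwards as well, with 1, 0 and 0 genes rising over all genes and 1, 0 and 3 adjusted over the list alone. The macrophage marker Csf1r rose (2.41 ± 0.44 SE, adjusted p = 0.0426), and Lyz2 had 10.8 and 11.1 CPM in vehicle and 222 and 25.01 CPM under TAK-981 (adjusted p = 0.199). Each of these 10 lists had an adjusted p of 0.849 with an estimated correlation. The MHC class II list was kept only without TAK-981 2, with a median of -0.16 without TAK-981 1 and adjusted p of 0.0926 without vehicle 1 and 0.235 without vehicle 2. Without vehicle 2 the T cell effector (1.72), inflammatory macrophage (1.01), monocyte (1.17) and inflammatory fibroblast lists (0.79) were not called, and the lipid-associated median was 0.41. Without TAK-981 1 the T cell effector list was not called (1.67), and medians were 0.98 for inflammatory macrophage, 0.80 for monocyte, 0.63 for inflammatory fibroblast and 0.97 for neutrophil activation genes, 1.03 for macrophage and 0.87 for neutrophil markers. Without vehicle 1 the acinar markers were at 9.46 and inflammatory fibroblast genes at 2.21. Csf1r kept its call only without TAK-981 2. The neutrophil marker list was not called without doublet removal (0.47) or at 1000 UMIs per cell (1.25), nor MHC class II with the length trend removed (2.46).

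Across epithelial-like cells 120 genes were higher and 286 lower of 12745 tested, and the libraries of the groups did not overlap for 53.8% of genes, where chance gives 33.3%. When transcripts under 800 nt were left out 35 were higher and 50 lower, and with the length trend removed 61 were higher and 45 lower. Short transcripts were 57.3% of the lower genes but 7.5% of the higher genes, against 7.38% of tested genes. Without them 2 of the 11 fitted named rises passed, at log2 fold changes of 1.29 to 2.69, and why the rises lost their calls was not tested. Of the 12 named rises, 3 passed with the length trend removed (P3h4, Fxyd5 and Vasp), although the log2 fold changes of all 12 stayed at 1.24 to 2.71. Without vehicle 1, vehicle 2, TAK-981 1 and TAK-981 2, 4, 3, 3 and 9 of these rises passed. A cluster led by Prl held 416 and 1199 vehicle cells against 26 and 71 TAK-981 cells. A change within cells and a change in which epithelial-like cells were present were not separated. Without vehicle 1, vehicle 2, TAK-981 1 and TAK-981 2 the counts were 333, 263, 242 and 464.

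In macrophage-like cells the MHC class I gene H2-T22 and the purinergic receptor gene P2rx7 rose under TAK-981. H2-T22 (ENSMUSG00000056116, chromosome 17 from 36037128 to 36042747) had 35.3 and 25.8 CPM in vehicle and 102 and 131 CPM under TAK-981 (log2 fold change 1.91 ± 0.25 SE, n = 2, edgeR adjusted p = 0.0260). P2rx7 (ENSMUSG00000029468, chromosome 5 from 122643911 to 122691432) rose from 42.1 and 34.2 CPM to 92.4 and 109.7 CPM (1.40 ± 0.22 SE, n = 2, adjusted p = 0.0324). Atp1b3 rose too (1.57 ± 0.24 SE, adjusted p = 0.0307), and Hist1h4d fell (-3.23 ± 0.32 SE, adjusted p = 0.0227) from 76.7 and 52.4 CPM to 8.43 and 5.31 CPM. Each of the 7 named rises and 12 named falls lost its call without vehicle 1 and without vehicle 2. A macrophage-like cluster with a median of 783 UMIs and Malat1 in 40.35% of cells held 117 of 1398, 50 of 738, 307 of 761 and 39 of 575 cells of the 4 libraries. Without clusters low in Malat1 6 rises and 12 falls passed. In all, 12 genes were higher and 90 lower of 10548, with 46.2% of genes not overlapping where chance gives 33.3%, and 27 and 185 genes passed without TAK-981 1 and TAK-981 2. Without vehicle 1 or vehicle 2 edgeR called 0 genes, where all 4 libraries gave 1425 genes at an unadjusted p under 0.05 and DESeq2 called 268. The counts were 4 higher and 13 lower without transcripts under 800 nt, where 1 of the 7 named rises passed at log2 fold changes of 1.39 to 2.08, and 25 higher and 24 lower with the length trend removed. P2rx7 was not called at 10% mitochondrial UMIs (1.32) or without transcripts under 800 nt (1.39), nor was Atp1b3 in the second (1.56).

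Interferon and MHC class I genes were higher in macrophage-like cells. Type I interferon genes had a median of 1.17 over 38 genes (camera adjusted p = 8.07e-11, 0.849 with an estimated correlation), which was 0.37 without TAK-981 2, 0.58 without vehicle 2 and 2.22 without vehicle 1. A macrophage-like cluster led by Ifit2, Rsad2 and Cxcl10 held 20 and 1 vehicle cells and 18 and 88 TAK-981 cells. Mean log2 CPM over the list was 5.53 and 4.00 in vehicle and 5.59 and 6.70 under TAK-981, with TAK-981 1 near vehicle 1. The gene that rose over all genes, and adjusted over the list alone, was Ifit3b, from 0.249 and 0 CPM to 15.2 and 33.4 CPM (7.01 ± 0.83 SE, adjusted p = 0.0260), a call lost without either vehicle library. Interferon-gamma genes had a median of 0.88 over 23 (adjusted p = 1.28e-09, 0.849 with an estimated correlation), 2.05 without vehicle 1 and 0.55 without vehicle 2, with 0 passing over all genes and 3 rising adjusted over the list alone, and Gbp8 had a log2 fold change of 2.08 (adjusted p = 0.0577). MHC class I genes had a median of 0.83 over 22 (adjusted p = 7.00e-13, 0.849 with an estimated correlation), with 1 rising over all genes and 8 adjusted over the list alone. H2-D1 had 821 and 764 CPM in vehicle and 1707 and 1686 CPM under TAK-981 (1.10 ± 0.25 SE, adjusted p = 0.105).

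Monocyte and immediate early genes were lower in macrophage-like cells as lists, with 0 genes passing over all genes. Monocyte genes had a median of -0.69 over 14 (camera adjusted p = 0.00359) and 4 fell adjusted over the list alone, where Fn1 had 2707 and 1835 CPM in vehicle and 850 and 907 CPM under TAK-981 (-1.37 ± 0.29 SE, adjusted p = 0.0858). The list was not called without vehicle 1 (-0.49) and stood at -1.05 without TAK-981 2. A macrophage-like cluster led by Ccr2 and Vcan held 834 of 1398 and 188 of 738 macrophage-like cells in vehicle and 51 of 761 and 104 of 575 under TAK-981. Immediate early genes of dissociation had a median of -0.49 over 19 (adjusted p = 9.46e-06) and 5 fell adjusted over the list alone, with Dusp1 at -1.20 (0.0789) and Nr4a1 at -1.91 (0.105), and the median was -0.96 without TAK-981 2. NF-kB targets (-0.35 over 19, adjusted p = 0.00640), T cell exhaustion genes (-0.59 over 6, 0.0205), naive T cell genes (-0.68 over 8, 0.0340) and B cell activation genes (-0.41 over 17, 0.0273) were called downwards, with 0, 2, 1 and 1 genes falling adjusted over the list alone. These 4 lists were not called without vehicle 1 (-0.11, -0.41, -0.81 and -0.17) or without TAK-981 1 (-0.26, -0.47, -0.07 and -0.26). Without vehicle 2 the NF-kB and B cell medians were -0.65 and -0.66, and without TAK-981 2 the exhaustion and naive T cell medians were -0.89 and -1.72. G2 and M phase genes (0.37 over 31, 0.00124) and heat shock genes (0.44 over 15, 0.00819) were called upwards. The G2 and M phase median was -0.21 without TAK-981 1 and 0.83 without TAK-981 2, and the heat shock list was not called without vehicle 2 (0.42) or TAK-981 2 (0.48) and stood at 0.91 without vehicle 1 and 0.88 without TAK-981 1. Heat shock genes were also not called at 10% mitochondrial UMIs (0.302), 1000 UMIs per cell (0.295) or Leiden resolution 2.0 (0.296). Acinar markers had a median of 3.48 over 12 genes (adjusted p = 7.09e-17), of which Cela2a rose over all genes (5.92 ± 0.70 SE, adjusted p = 0.0260) and 9 rose adjusted over the list alone, and their median was 8.61 without vehicle 1. Cela2a lost its call without either vehicle library. RNA of acinar-like cells was not separated from a change of these genes in macrophage-like cells. Mitochondrial transcripts had a median of 0.82 over 11 (adjusted p = 0.0169), not called without vehicle 2 (0.715) or TAK-981 1 (0.69). The mitochondrial share of UMIs per cell was higher in both TAK-981 libraries. With an estimated correlation the adjusted p was 0.881 for G2 and M phase genes and 0.849 for the other 9 lists.

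In fibroblast-like cells the interferon-induced genes Rsad2 and Cxcl10 rose under TAK-981. Rsad2 (ENSMUSG00000020641, chromosome 12 from 26442746 to 26456452) had 0 and 2.01 CPM in vehicle and 55.9 and 148 CPM under TAK-981 (log2 fold change 6.25 ± 0.86 SE, n = 2, edgeR adjusted p = 0.0219). Cxcl10 (ENSMUSG00000034855, chromosome 5 from 92346638 to 92348889) rose from 37.7 and 12.04 CPM to 170.5 and 286.5 CPM (3.28 ± 0.53 SE, n = 2, adjusted p = 0.0311), 0.679 times the macrophage level. Ifit3b had 0 CPM in both vehicle libraries and a mean of 39.2 CPM under TAK-981, at least 22.8-fold higher than a floor of 3 counts (1.72 CPM). Hsd11b1 (3.22 ± 0.44 SE, adjusted p = 0.0180) and Mmp3 (2.52 ± 0.46 SE, adjusted p = 0.0361) rose as well. The mesothelial markers Lrrn4 (67.1 and 32.1 to 0 and 2.01 CPM, -5.43 ± 0.79 SE, adjusted p = 0.0180) and Upk3b (58.9 and 23.1 to 0 and 2.01 CPM, -5.14 ± 0.86 SE, adjusted p = 0.0302) fell. Fabp4 fell by 2.85 ± 0.34 SE (adjusted p = 0.0180), a gene with 0.0156 times the level of endothelial-like cells.

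Type I interferon genes had a median of 1.47 over 33 genes in fibroblast-like cells (camera adjusted p = 1.82e-18, 0.849 with an estimated correlation), with 2 rising over all genes and 12 adjusted over the list alone. The median was 0.71 without TAK-981 2. Interferon-gamma genes had a median of 1.30 over 18 (adjusted p = 1.02e-05, 0.849 with an estimated correlation), with Cxcl10 passing over all genes and 3 adjusted over the list alone, and 2.705 without vehicle 1, 0.58 without vehicle 2 and 0.62 without TAK-981 2. MHC class I genes had a median of 0.81 over 20 (adjusted p = 4.84e-10, 0.849 with an estimated correlation), with H2-T23 (1.88 ± 0.32 SE, adjusted p = 0.0218) and H2-D1 (1.82 ± 0.35 SE, 0.0361) rising over all genes and 7 adjusted over the list alone. Their median was 1.46 without vehicle 1, and H2-D1, Ccl6, Mmp3 and Prss2 were not called without vehicle 2. Chemokines had a median of 0.90 over 18 (7.56e-06), with Cxcl3, Ccl6 and Cxcl10 rising over all genes and 4 adjusted over the list alone, and 1.45 without vehicle 1 and 0.38 without vehicle 2. Inflammatory macrophage genes (0.44 over 7, 0.00640) and neutrophil activation genes (0.91 over 10, 0.000195) held Il1b, which rose (2.26 ± 0.34 SE, adjusted p = 0.0180) to 172 and 249.7 CPM, 0.00533 times its neutrophil level. Neutrophil RNA made up an estimated 0.057 and 0.086% of fibroblast RNA in vehicle and 0.287 and 0.423% under TAK-981. Such RNA was not separated from a change of Il1b in fibroblast-like cells. The inflammatory macrophage list was not called without vehicle 2 (0.145) or TAK-981 2 (0.795), with medians of 2.14 without vehicle 1 and 1.25 without TAK-981 1, and the neutrophil activation median was 1.46 without vehicle 1, 1.41 without TAK-981 1 and 0.45 without TAK-981 2. MHC class II (0.80 over 7, 0.0194), G2 and M phase (0.43 over 29, 0.0226), p53 target (0.42 over 19, 0.0130) and heat shock genes (0.77 over 15, 0.00107) were called upwards with 0 genes passing over all genes, against 856 fibroblast genes at an unadjusted p under 0.05. The MHC class II list was not called without vehicle 2 (0.17) or TAK-981 1 (0.29), nor the G2 and M phase list without vehicle 1 (0.56) or TAK-981 1 (-0.02), and without vehicle 1 the MHC class II median was 2.74. The G2 and M phase list was also not called without doublet removal (0.10), at 10% mitochondrial UMIs (0.33), at 1000 UMIs (0.04), at Leiden resolution 2.0 (0.32) or with thinned libraries (0.38). At Leiden resolution 2.0 MHC class II (1.02) and p53 genes (0.21) were not called. Without TAK-981 2 the p53 (0.23) and heat shock lists (0.15) were not called, nor p53 without vehicle 2 (0.33). The antigen-presenting fibroblast list, which holds the mesothelial markers, had a median of -0.72 over 13 (0.00359), with 2 falling over all genes and 3 adjusted over the list alone, but 0.50 and reversed at Leiden resolution 2.0 and -0.09 without vehicle 2. With an estimated correlation the adjusted p was 0.873 for G2 and M phase genes and 0.849 for the other lists.

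Markers of other cells moved in the fibroblast-like cells as well. Acinar markers had a median of 4.45 over 6 genes (camera adjusted p = 2.26e-17, 0.849 with an estimated correlation), where Ctrb1 (5.44 ± 0.73 SE, adjusted p = 0.0180) and Prss2 (5.91 ± 0.97 SE, 0.0271) rose, with a list median of 7.10 without vehicle 1. Macrophage markers had a median of 3.83 over 6 (6.35e-06, 0.849 with an estimated correlation), with 0 passing over all genes, 2 adjusted over the list alone and 2.10 without TAK-981 1, and macrophage RNA made up an estimated 0.442, 0.168, 4.16 and 1.01% of fibroblast RNA in the 4 libraries. Of the 12 named rises, 4 remained in a fit without genes that other cells could supply (Cxcl10, Hsd11b1, AW011738 and Mmp3). In all, 22 genes were higher and 90 lower of 8940 tested, with 40.7% not overlapping where chance gives 33.3%. Without transcripts under 800 nt 10 were higher and 13 lower, and with the length trend removed 7 were higher and 9 lower, where Rsad2 in fibroblast cells (adjusted p = 0.0552) and Cxcl10 in fibroblast cells (0.213) no longer passed at log2 fold changes of 6.28 and 3.097. The 12 named rises stood at 2.03 to 6.28. Rsad2 was 4.12 (0.313) at Leiden resolution 2.0, and Cxcl10 was 2.74 (0.271) without doublet removal, 3.11 (0.0916) at 10% mitochondrial UMIs, 3.09 (0.223) at 1000 UMIs per cell and 3.27 (0.0508) without transcripts under 800 nt. Lrrn4 and Upk3b lost their calls without doublet removal (-5.42 and -4.35) and at 1000 UMIs per cell (-5.35 and -4.585). Hsd11b1 lost it at 10% mitochondrial UMIs (2.55) and 1000 UMIs per cell (2.415). Without vehicle 1, vehicle 2, TAK-981 1 and TAK-981 2 the counts were 268, 115, 170 and 234.

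Cd8a in T or NK cells rose under TAK-981, as did Bst2 in T or NK cells and Psmb8 in T or NK cells. Cd8a (ENSMUSG00000053977, chromosome 6 from 71373427 to 71379173) had 37.4 and 36.2 CPM in vehicle and 233 and 167 CPM under TAK-981 (log2 fold change 2.41 ± 0.45 SE, n = 2, edgeR adjusted p = 0.0466). Bst2 (ENSMUSG00000046718, chromosome 8 from 71534255 to 71537456) rose from 32.0 and 48.3 CPM to 193 and 218 CPM (2.43 ± 0.44 SE, n = 2, adjusted p = 0.0466), a call lost without vehicle 1 (0.0533), and the immunoproteasome gene Psmb8 rose from 272 and 338 CPM to 952 and 818 CPM (1.55 ± 0.31 SE, adjusted p = 0.0499), a call lost without vehicle 1 (0.0790). At 1000 UMIs per cell 0 genes were called higher, with Bst2 at 2.65 (0.0806) and Psmb8 at 1.56 (0.110). Psmb8 was also not called with thinned libraries (1.51, 0.0532), without transcripts under 800 nt (1.54, 0.117) or with the length trend removed (1.31, 0.0955). The Cd8a call was lost with libraries thinned to equal macrophage depth (2.29, 0.0560), with at least 1000 UMIs per cell (2.81, 0.0895) and without transcripts under 800 nt (2.40, 0.117), with fold changes near that of the reported fit and adjusted p in a range from 0.000107 to 0.120 over its alternatives. Hcst, which encodes an adaptor of activating receptors, fell (-2.53 ± 0.33 SE, adjusted p = 0.0172) and is a transcript of 442 nt. In all, 4 genes were higher and 23 lower of 4339 tested, with 45% not overlapping where chance gives 33.3%. Without transcripts under 800 nt edgeR called 0 genes, where 552 genes had an unadjusted p under 0.05 with all transcripts and DESeq2 called 53, and with the length trend removed 6 were higher and 10 lower. Without vehicle 1, vehicle 2, TAK-981 1 and TAK-981 2 the counts were 118, 125, 71 and 191.

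The type I interferon list in T or NK-like cells had a median of 0.88 over 16 genes (camera adjusted p = 0.00176, 0.849 with an estimated correlation), with Bst2 rising over all genes and adjusted over the list alone. Without TAK-981 2 its median was 0.32 and it was not called (adjusted p = 0.298), and it was 1.39 without TAK-981 1. The median was 0.415 (adjusted p = 0.0166) with libraries thinned to equal macrophage depth and 0.47 at 1000 UMIs per cell. Mean log2 CPM over the list was 6.52 and 5.99 in vehicle and 6.61 and 7.40 under TAK-981, so TAK-981 1 lay near vehicle 1. MHC class I genes had a median of 0.51 over 22 (0.000290), with Psmb8 rising over all genes and 4 adjusted over the list alone. Genes of naive and memory T cells had a median of -0.93 over 11 (0.00881) and 0 passing, with Tcf7 at 299 and 157 CPM in vehicle and 25.9 and 152 CPM under TAK-981 (-1.36 ± 0.78 SE, adjusted p = 0.552) and S1pr1 at -1.88 ± 0.62 SE (0.276). A T cell cluster with Tcf7 and S1pr1 among its top genes held 49 and 13 vehicle cells against 0 and 1 TAK-981 cells. A cluster led by Ccl1 and Ccl3 held 5 and 0 against 31 and 37. For the genes and lists of this class, a change within cells and a change in which cells were present were not separated. The naive and memory genes were not called without vehicle 1 (-0.31) or TAK-981 1 (-0.22), and stood at -1.84 without TAK-981 2. G2 and M phase genes had a median of 0.60 over 13 (0.00359) and 2 rising adjusted over the list alone, with Cks1b at 2.13 ± 0.56 SE (0.128), and were not called without TAK-981 1 (0.28), with medians of 0.26 without vehicle 2, 1.16 without TAK-981 2 and 1.22 without vehicle 1. Lipid-associated macrophage genes (0.76 over 9, 0.0249) and heat shock genes (0.40 over 11, 0.0340) were called upwards with 1 gene each adjusted over the list alone. The first was not called upwards without vehicle 1 (0.20), TAK-981 1 (0.62) or TAK-981 2 (0.47), and the second not without vehicle 2 (0.22) or TAK-981 2 (-0.08). The adjusted p of these lists was 0.849 with an estimated correlation.

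In neutrophil-like cells the interferon-induced genes Ifit3, Zbp1 and Rtp4 rose and Chil3 fell, in 38 and 39 TAK-981 cells. Ifit3 (ENSMUSG00000074896, chromosome 19 from 34583531 to 34588731) rose from 19.7 and 3.85 CPM to 380 and 616.5 CPM (log2 fold change 5.22 ± 0.65 SE, n = 2, edgeR adjusted p = 0.0108), Zbp1 by 4.25 ± 0.65 SE (0.0169) and Rtp4 by 4.42 ± 0.82 SE (0.0374), the last 2 not called without TAK-981 1 or TAK-981 2. Chil3 (ENSMUSG00000040809, chromosome 3 from 106147554 to 106167564) had 1207 and 2743 CPM in vehicle and 0 in both TAK-981 libraries, at least 78.2-fold lower against a floor of 3 counts over the group (25.3 CPM, adjusted p = 0.0108). Tnfaip2, an NF-kB target, fell from 3042 and 1847 CPM to 364.5 and 272 CPM (-2.94 ± 0.55 SE, adjusted p = 0.0374), a call lost without TAK-981 1 and without TAK-981 2. Without doublet removal edgeR called 0 neutrophil genes, where the fit with it gave 338 genes at an unadjusted p under 0.05 and DESeq2 called 47, and Ifit3 in neutrophils then had an adjusted p of 0.0889 and Chil3 in neutrophils one of 0.442. Over their alternatives the adjusted p ranged up to 0.195 for Ifit3 and 0.442 for Chil3. The Chil3 change was -2.43 without doublet removal, -2.48 at 10% mitochondrial UMIs, -2.68 with thinned libraries and -5.44 at 1000 UMIs per cell, without a call in each. The bound above held only for the cells of the reported fit. At 1000 UMIs per cell and with thinned libraries 0 of the named rises and falls passed. In all, 16 genes were higher and 2 lower of 2211 tested, with 46.4% not overlapping where chance gives 33.3%, 6 higher and 1 lower without transcripts under 800 nt, and 16 higher and 4 lower with the length trend removed. Without vehicle 1, vehicle 2, TAK-981 1 and TAK-981 2 the counts were 67, 53, 6 and 14.

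Type I interferon genes had a median of 2.34 over 25 in neutrophil-like cells (camera adjusted p = 8.34e-23, 0.849 with an estimated correlation), with 5 rising over all genes and 19 adjusted over the list alone, and 3.77 without vehicle 1 and 1.52 without vehicle 2. MHC class I genes had a median of 0.77 over 13 (0.000214), 1.82 without vehicle 1, and 4 rising adjusted over the list alone. NF-kB targets had a median of -0.82 over 15 (0.000290), with Tnfaip2 falling over all genes and 3 adjusted over the list alone. Inflammatory macrophage genes had a median of -0.87 over 8 (0.0130), where Il23a had 920 and 708 CPM in vehicle and 31.7 and 163 CPM under TAK-981 (-3.10 ± 0.62 SE, adjusted p = 0.0561), and were not called without vehicle 1 (-0.55), TAK-981 1 (-0.96) or with thinned libraries (-0.68), and stood at -1.42 without vehicle 2. Neutrophil activation genes had a median of -0.28 and a mean of -1.40 over 20 (0.0159), with 4 falling adjusted over the list alone, Icam1 at -2.48 (0.120) among the lowest. They were not called without vehicle 1 (0.17) or TAK-981 1 (-0.40), and stood at -0.90 without vehicle 2 and -0.92 without TAK-981 2. Lipid-associated macrophage genes had a median of 1.54 over 11 (1.94e-06) with 8 rising adjusted over the list alone, beside macrophage markers at 1.61 over 6 (0.00675), of which C1qb rose (2.83 ± 0.53 SE, adjusted p = 0.0374). Without TAK-981 2 the macrophage markers (0.58) and C1qb were not called and the lipid-associated median was 0.97. Mitochondrial transcripts had a median of 1.52 over 11 (0.00682), with 8 rising and 1 falling adjusted over the list alone and no call without TAK-981 1 (0.785), and the acinar genes Try5, Ctrb1 and Cela3b rose by 6.15, 6.12 and 5.69. The mitochondrial share per cell also differed between the groups. The call of Ctrb1 was lost without TAK-981 1 and that of Cela3b without either vehicle library. Acinar-like cells numbered 15 and 0 in vehicle and 171 and 41 under TAK-981, and their RNA in neutrophil droplets was not tested. Of the 5 named rises, 2 were fitted without genes that other cells could supply, at log2 fold changes of 5.225 and 5.455. With an estimated correlation the adjusted p of these lists was 0.849.

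**Figure D2:**
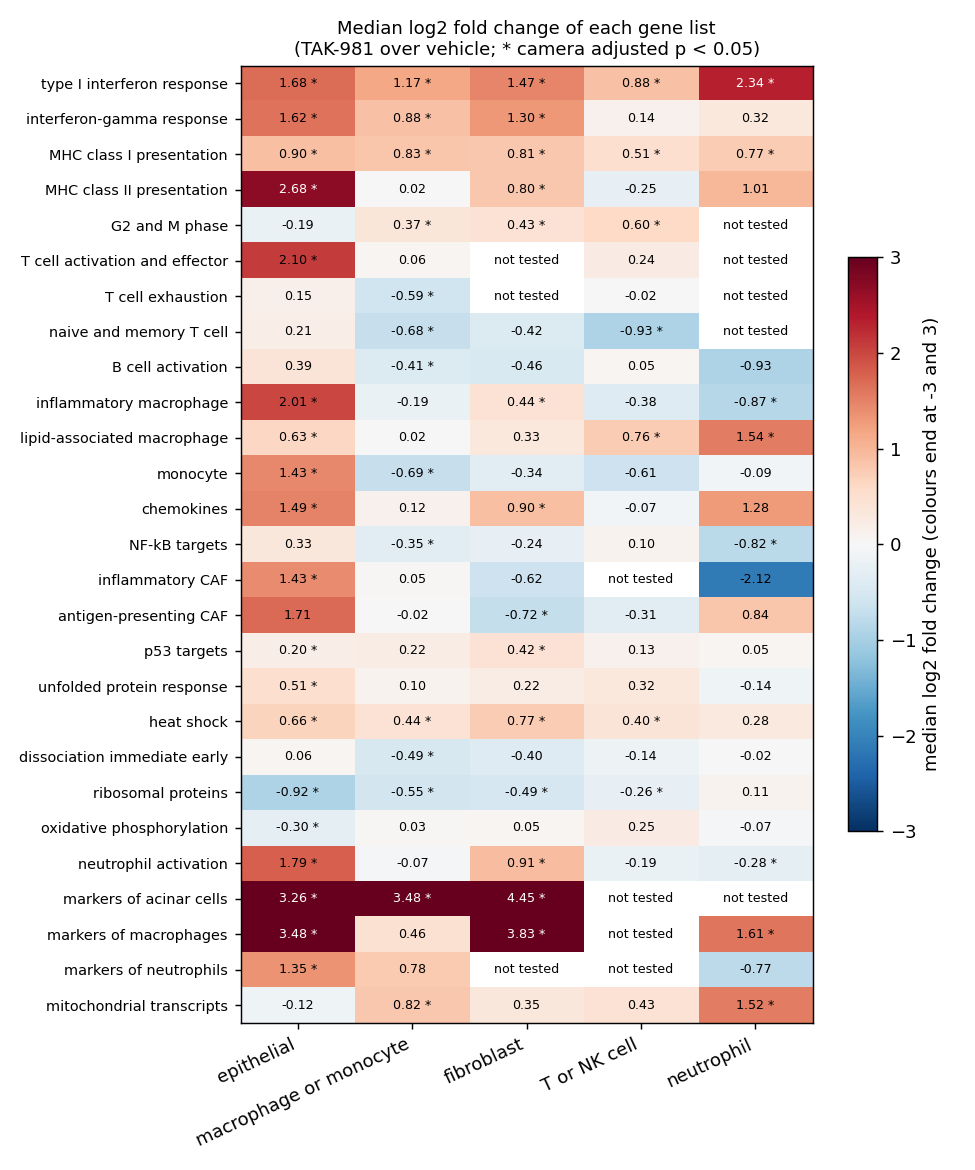
Median log2 fold change (TAK-981 over vehicle, colours end at -3 and 3) of each gene list called in at least 1 class, for the 5 classes tested, where a star marks a camera adjusted p under 0.05 at the preset correlation. The type I interferon medians are 1.68, 1.17, 1.47, 0.88 and 2.34 in epithelial, macrophage, fibroblast, T or NK and neutrophil-like cells.

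Short transcripts made up most of the genes that fell in 4 of the 5 classes, ribosomal protein genes such as Rps28, Rpl38 and Rps29 among them. Rps28 (ENSMUSG00000067288, 271 nt, chromosome 17 from 33819027 to 33824562) had 9946 and 8657 CPM in epithelial vehicle cells and 580.5 and 1352 CPM under TAK-981 (-3.27 ± 0.45 SE, n = 2, edgeR adjusted p = 0.0250), a call lost without vehicle 1 (0.0693) and without vehicle 2 (0.0730). With the length trend removed Rps28 in epithelial cells was 0.09 (adjusted p = 0.850) and Rps28 in fibroblast cells 0.07. Transcripts under 800 nt were 57.3% of lower genes in epithelial-like cells (164 of 286), 72.2% in macrophages (65 of 90), 73.3% in fibroblasts (66 of 90) and 69.6% in T or NK-like cells (16 of 23), against 7.38, 6.21, 5.75 and 8.83% of tested genes. Depth and the mitochondrial share per cell differed between the groups as well. S100a4 (498 nt, -2.79 ± 0.32 SE, adjusted p = 0.0116) and Crip1 (445 nt, -2.65 ± 0.39 SE in macrophages, 0.0307) fell along with respiratory chain genes such as Cox6c (503 nt, -2.33 ± 0.23 SE in epithelial-like cells, 0.0116). Pet100 fell in epithelial-like cells (-3.20 ± 0.35 SE, adjusted p = 0.0116), macrophages (-2.53 ± 0.33 SE, 0.0266) and fibroblasts (-2.45 ± 0.37 SE, 0.0180), and kept its call in all 3 with the length trend removed.

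Ribosomal protein genes were lower as a list in 4 classes, with medians over 34 genes of -0.92 in epithelial-like cells (camera adjusted p = 1.82e-18, 14 falling over all genes and 20 adjusted over the list alone), -0.55 in macrophages (7.24e-09, 4 and 14), -0.49 in fibroblasts (1.94e-06, 3 and 13) and -0.26 in T or NK-like cells (0.0102, 1 and 7). With an estimated correlation the adjusted p was 0.904 in T or NK-like cells and 0.849 in the other 3. Ribosomal proteins with short transcripts had medians of -2.003, -1.48, -1.49, -1.40 and -1.05 in epithelial, macrophage, fibroblast, T or NK and neutrophil-like cells, and those with long transcripts -0.44, -0.11, -0.07, 0.08 and 0.20. Without transcripts under 800 nt the list was not called in fibroblasts (median 0.10, adjusted p = 0.0951) or T or NK-like cells (0.25, 0.893), but stayed called in epithelial-like cells (-0.45, 7.87e-08) and macrophages (-0.06, 0.0146). With the length trend removed it was called in all 4, at -0.31, -0.19, -0.13 and -0.06. Without vehicle 2 it was -0.36 in macrophages and -0.18 in fibroblasts, where it was -0.74 without vehicle 1, and in T or NK-like cells it was not called without vehicle 2 (-0.05, 0.147) or TAK-981 1 (0.01, 0.329). Oxidative phosphorylation genes had a median of -0.30 over 25 in epithelial-like cells (0.000214, 0.849 with an estimated correlation), with 6 falling over all genes and 7 adjusted over the list alone, and -0.47 without TAK-981 1.

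**Figure D3:**
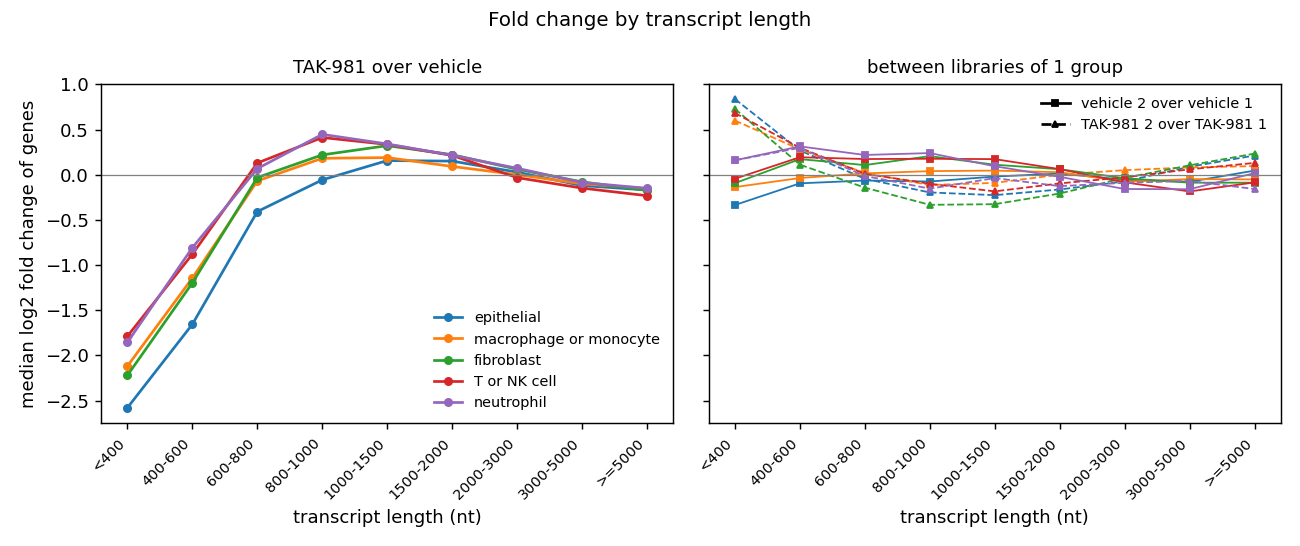
Median log2 fold change of genes (vertical axis) by transcript length in nt (horizontal axis), for TAK-981 over vehicle on the left and between the libraries of 1 group on the right, with 1 colour per class. Genes under 400 nt lie at -2.58 in epithelial-like cells for TAK-981 over vehicle, and at 0.84 for TAK-981 2 over TAK-981 1.

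Of the SUMO pathway, the target of the drug, Sumo3, Sumo2, Sae1 and Uba2 did not pass in epithelial-like cells. Sumo3 in epithelial-like cells had 52.3 and 56.6 CPM in vehicle and 107 and 102 CPM under TAK-981 (0.94 ± 0.21 SE, n = 2, edgeR adjusted p = 0.0650), and in macrophages 0.98 ± 0.20 SE (0.0836). Sumo2 was 0.42 ± 0.23 SE (0.348), Sae1 0.47 ± 0.21 SE (0.260) and Uba2 0.40 ± 0.23 SE (0.365) in epithelial-like cells. As a list SUMO genes had medians from 0.18 to 0.49 and a smallest adjusted p of 0.0785. Of the 49 lists tested, 22 were called in none of the 5 classes, with medians from -0.86 to 1.82 and a smallest camera adjusted p of 0.0540. These included MYC targets, S phase, TGF-beta, hypoxia, apoptosis, cholesterol synthesis, epithelial to mesenchymal transition, classical and basal-like tumour genes, extracellular matrix, myofibroblast genes, angiogenesis, endothelial activation, alternatively activated macrophages, NK cytotoxicity, regulatory T cells, checkpoint ligands, SUMO genes and markers of T, epithelial and fibroblast cells. Markers of red cells, platelets and B cells had too few tested genes.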

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

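The tests of transcript length and of the neutrophil share, and those of length and depth for interferon genes, were chosen only after the result was seen, while the tests of RNA from other cells were written before. Inflammatory macrophage genes had list medians of 2.01 in epithelial-like and -0.87 in neutrophil-like cells, a difference of 2.88 on the log2 scale, with 0 of 12 and 0 of 8 genes passing over all genes. The list was not called without vehicle 2 in the first class, nor without vehicle 1 or TAK-981 1 in the second. Neutrophil activation genes had medians of 1.79 in epithelial-like and 0.91 in fibroblast-like cells against -0.28 in neutrophil-like cells, differences of 2.07 and 1.20, and the neutrophil call was lost without vehicle 1 (0.17) and without TAK-981 1. In each case both TAK-981 libraries lay on opposite sides of both vehicle libraries in the 2 classes, and the difference itself was not tested. Each adjusted p was 0.849 with an estimated correlation. In epithelial-like and fibroblast-like cells the genes of these lists lay beside higher markers of macrophages, so RNA from other cells was not excluded for them.

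Short transcripts were lower in both TAK-981 libraries in every tested class. In epithelial-like, macrophage-like and fibroblast-like cells, genes under 600 nt outside the ribosome and the respiratory chain had a median log2 fold change of -0.91 in the class nearest 0, which is consistent with a length bias between the libraries. A single bound of -0.5 for all 5 classes was set first. It was not met in T or NK-like cells (-0.39) and neutrophil-like cells (-0.32), and the classes were split after that. The value of -0.317 with intervals from -0.735 to -0.166 and from -0.805 to -0.062 leaves those 2 classes open. These intervals, and those below, come from 10000 bootstrap draws of the genes of a class. Genes of the same 4 libraries are not replicates, so the intervals carry no spread between tumours. Lower mitochondrial ribosome and respiratory chain RNA whatever its length was argued against, since members of 800 nt or more had a median of -0.101 in the lowest class, as was lower ribosomal protein RNA in T or NK-like and neutrophil-like cells, with such members at 0.082 or more, but not in epithelial-like cells (-0.438, interval -1.026 to -0.33) or in macrophage-like and fibroblast-like cells (-0.113 in the lower, interval -0.606 to 0.036), where it stays open. An effect of TAK-981 on short transcripts cannot be told apart from library preparation, since each library belongs to 1 group and libraries of 1 group already differed by up to 0.838 for genes under 400 nt.

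Type I interferon response genes were higher in both TAK-981 libraries in all 5 tested classes, although TAK-981 1 lay near vehicle 1 in macrophage-like cells (mean log2 CPM 5.59 and 5.53) and in T or NK-like cells (6.61 and 6.52). In epithelial, fibroblast and T or NK-like cells the list's median was 6.47, 14.97 and 58.16 times the level brought by macrophage and neutrophil RNA. In neutrophil-like cells it was 26.73 times that of macrophage RNA. These ratios compare whole levels and not the rise. Without genes other cells could supply, list medians were 0.67 or more (epithelial 0.77, from 1.68), which argues against such RNA as the whole cause. The list median in the class nearest 0 was 0.79 with the length trend removed, which argues against length as the whole cause. With libraries thinned to equal macrophage depth the median was 1.053 or more in 4 classes and 0.415 in T or NK-like cells. Thinning lowers all genes alike and hardly moves scaled values, so it cannot decide on depth, which stays open. A treatment effect may be a candidate explanation outside T or NK-like cells, a hypothesis found and tested on the same 4 tumours. It stays open because batches following the groups have no test here, and because an Ifit2-led macrophage-like cluster held 20, 1, 18 and 88 cells. An estimated correlation called 0 lists, but whether it can call a raised list was not tested.

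The neutrophil share was lower in both TAK-981 libraries. Clusters under their best-scoring name gave a difference of -11.52 percentage points and the share among immune cells differed by -20.39, which argues against unnamed neutrophil-like cells and more tumour cells as whole causes. Libraries thinned to equal macrophage depth gave -8.26, but TAK-981 neutrophils were the deeper ones, so thinning could not raise their share and decides nothing. The neutrophil-like cells kept had medians of 659 and 621 UMIs in vehicle against 1615.5 and 1465 UMIs under TAK-981. A minimum of 500 UMIs takes more cells from shallower libraries. For the cells kept, these depths argue against that minimum as the cause of a lower share under TAK-981. With at least 1000 UMIs per cell the difference was 0.450, from 89, 75, 40 and 103 cells. Best-scoring names alone gave 758, 458, 43 and 103 cells, so naming alone did not remove the difference. Loss of cells during dissociation or removal of dead cells, which the labels give only for samples of low viability, may contribute and was not tested, and a treatment effect stays open beside it.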

How the results depend on the processing

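The fits by transcript length, thinned depth, Malat1 content, best-scoring names and the Epcam-led cluster were chosen only after the data had been seen. Directions and calls were kept in 5010 of 5836 comparisons of single genes and 945 of 1170 of single lists. The genes included some not called in the reported fit. A gene called in neither fit, with the same direction, counted as kept, so the first count does not measure how often calls held. The lists were those called in the reported fit. Of 130 comparisons of class shares 124 counted as kept and 6 moved by more than the spread between replicates. Of 48 comparisons of subclass shares 34 counted as kept, 12 moved and 2 passed a threshold. A share that changed direction within that spread counted as kept. The edgeR tests of cell numbers were judged by direction and threshold alone. Among single genes 398 lost and 403 gained a call and 3 reversed, and among lists 220 lost a call and 5 reversed. Where no value shows why a result moved, the cause was not tested.

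Gene counts in epithelial, macrophage, fibroblast, T or NK and neutrophil-like cells were 1809, 679, 385, 118 and 98 without a filter on low counts. They were 85, 17, 23, 0 and 7 without transcripts under 800 nt, and 106, 49 and 16 in the first 3 classes and 16 in T or NK-like cells with the length trend removed. The DESeq2 Wald test gave 1274 genes in epithelial-like cells, 268 in macrophages, 53 in T or NK-like cells and 47 in neutrophils. T or NK-like cells gave 44 genes without genes that other cells could supply, 56 without doublet removal, 67 at a limit of 10% mitochondrial UMIs, 2 at 1000 UMIs per cell and 54 with thinned libraries. Neutrophils gave 0 genes by edgeR without doublet removal, at 1000 UMIs per cell and with thinned libraries, against 338 at an unadjusted p under 0.05 in the reported fit, and 8 with clusters under their best-scoring name. Leaving out each library gave 242 to 464, 0 to 185, 115 to 268, 71 to 191 and 6 to 67 genes, where a lone library was assumed to vary like the other group.

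Called lists numbered 0 in each of the 5 classes with camera at an estimated correlation. They also numbered 0 in each by fry, which tests whether a list's genes move one way. Neither test was run on the simulated data, so whether it could call a raised list here was not tested. Without genes that other cells could supply 9 lists were called in epithelial-like and 9 in fibroblast-like cells. Without a filter 22 were called in macrophages and 14 in T or NK-like cells, and with thinned libraries 5 in neutrophils. Leaving out each library gave 18 to 24, 14 to 22, 16 to 18, 7 to 9 and 6 to 13 lists. The antigen-presenting fibroblast list reversed to a median of 0.50 (adjusted p = 0.00879) at Leiden resolution 2.0, and the mitochondrial transcripts list in neutrophils had a median of 0.33 at 1000 UMIs per cell with the test reversed. With the length trend removed Rps28 in epithelial cells was 0.088, Uqcrq in epithelial cells 0.52 and Rps28 in fibroblast cells 0.068. Without TAK-981 1 the G2 and M phase list in macrophage or monocyte cells reversed (medians from -0.213 to 0.829 over the 4 libraries left out), as did the G2 and M phase list in fibroblast cells (-0.018 to 0.807). Without vehicle 1 the lipid-associated macrophage list in T or NK-like cells reversed by its test (medians from 0.203 to 0.845).

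Differences in share, in percentage points, were 7.37 for T or NK-like cells, 22.7 for macrophages and -20.4 for neutrophils among immune cells, 0.689 for epithelial-like cells without doublet removal, and for neutrophils -11.5 under best-scoring names and 0.450 at 1000 UMIs per cell. CD4-like cells differed by 0.518 at 10% mitochondrial UMIs, -3.11 at 1000 UMIs, 28.8 with interferon and MHC genes left out of clustering and 9.61 with thinned libraries. CD8-like cells differed by -5.81 without doublet removal, 17.8 at 10% mitochondrial UMIs, -12.2 at 1000 UMIs, 2.14 with interferon and MHC genes left out of clustering and 2.40 with thinned libraries. Regulatory T-like cells differed by 4.75 with thinned libraries and had a log2 ratio of -7.49 by edgeR (adjusted p = 0.00102), which a prior count set since TAK-981 cells numbered 0. Leaving out each library gave -9.48 to -0.087 for B-like, 0.298 to 2.26 for T or NK-like, 1.15 to 7.55 for acinar-like, -3.77 to 0.469 for dendritic-like, -1.28 to -0.031 for endothelial-like, 5.14 to 30.4 for epithelial-like, -2.20 to 1.01 for fibroblast-like, -6.30 to 9.58 for macrophage-like and -10.7 to -7.62 for neutrophil-like cells. Among T or NK-like cells it gave 15.0 to 25.2 for CD4-like, 4.07 to 6.60 for CD8-like, -18.5 to -4.27 for NK-like and -25.8 to -13.2 for regulatory T-like cells.

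The replicate numbers were also entered as a block, although the labels name no pairing. For each gene, the deviation of a library from the mean of its group was taken. Between libraries with the same number these deviations correlated by -0.035, -0.098, -0.119, -0.139 and -0.221 across genes in the 5 classes, which gives no sign of pairing. The block gave 56 genes in macrophages and 0 in T or NK-like cells, Cd8a included, and in neutrophils, where edgeR without it found 552 and 338 genes at an unadjusted p under 0.05, and a log2 ratio of -7.27 (adjusted p = 0.0152) for regulatory T-like cells.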

Other observations

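The tests of endothelial-like and dendritic-like cells were chosen only after the data had been seen. In endothelial-like cells Bst2 rose from 294 and 106 CPM to 1027 and 709 CPM (log2 fold change 2.15 ± 0.45 SE, n = 2, edgeR adjusted p = 0.0123), and endothelial-like cells held its highest level of all classes. Type I interferon genes had a median of 0.62 over 28 genes (camera adjusted p = 1.81e-05, 0.817 with an estimated correlation), with Bst2 the gene that passed over all genes. MHC class I genes had a median of 1.14 over 19 (7.83e-10, 0.796 with an estimated correlation), with 4 rising over all genes and 9 adjusted over the list alone. MHC class II genes had a median of 3.66 over 5 (1.44e-15, 0.616 with an estimated correlation), and Cd74 rose from 28.0 and 20.6 CPM to 542 and 427 CPM (4.33 ± 0.45 SE, adjusted p = 8.3e-05). The macrophage gene Lyz2 rose beside them from 9.32 and 51.4 CPM to 739 and 660 CPM (4.42 ± 0.51 SE, adjusted p = 0.000425), as did the acinar gene Ctrb1, with 0 UMIs in both vehicle libraries. TAK-981 2 held 16 endothelial-like cells, and in all 60 genes were higher and 117 lower of 4685 tested.

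In dendritic-like cells Ccl2 (20.8 and 12.3 to 278 and 275 CPM, 3.82 ± 0.43 SE, n = 2, edgeR adjusted p = 0.000204) and H2-M2 (28.3 and 0 to 294 and 138 CPM, 3.23 ± 0.61 SE, adjusted p = 0.0108) rose. The macrophage gene Lyz2 rose from 306 and 123 CPM to 1746 and 1140 CPM (2.62 ± 0.40 SE, adjusted p = 0.00281). Lipid-associated macrophage genes had a median of 0.98 over 12 (camera adjusted p = 8.49e-05), beside macrophage markers at 1.43 over 6 (0.0270). SUMO pathway genes had a median of 0.54 over 11 (0.0107) with 0 genes passing by edgeR, where 477 dendritic genes had an unadjusted p under 0.05. Ribosomal protein genes had a median of -0.65 (1.90e-09), with 15 falling over all genes. Each of these lists had an adjusted p of 0.978 with an estimated correlation. The type I interferon list was not called (median -0.22, adjusted p = 0.464). In all, 21 genes were higher and 143 lower of 3310 tested, with 34, 38 and 27 cells in vehicle 2 and the TAK-981 libraries.

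Epithelial-like clusters differed in which tumours filled them. A cluster led by Prl, Cldn18 and Msln held 416 and 1199 vehicle cells and 26 and 71 TAK-981 cells, and a cluster led by Cenpf and Top2a, with Prl among its top genes, held 216 and 341 against 15 and 28. The cell cycle lists were not called over all epithelial-like cells, with medians of -0.19 for G2 and M phase (adjusted p = 0.298) and 0.42 for S phase (0.0688). A cluster led by Hspb1, Areg and Cxcl5 held 63 and 37 vehicle cells against 192 and 1030 TAK-981 cells, and 1 led by Ttr, Lbp and Hp held 12 and 0 against 306 and 194. A cluster led by Tff2 and Tff1 held 362 of its 377 cells in TAK-981 2. Of 2 unnamed clusters with myeloid genes, 1 led by Hcar2 and Ccl3 held 223, 82, 5 and 64 cells, and 1 with Arg1 and Nos2 held 105, 88, 11 and 95. A cluster of 1105 epithelial-like cells had Malat1 in 37.7% of cells, against 98.1% in the Prl-led cluster. Malat1 was also low in a macrophage-like cluster (40.35%), the acinar-like cluster (44.05%) and an unnamed cluster of 628 cells (49.04%).

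Xist UMIs were found in 71.9, 86.0, 54.8 and 83.9% of epithelial-like cells of vehicle 1, vehicle 2, TAK-981 1 and TAK-981 2, and UMIs of Y-linked genes in 1.3, 0.56, 5.3 and 2.55%. In macrophage-like cells the Xist shares were 2.15, 6.23, 2.89 and 7.3% and the Y-linked shares 40.9, 36.5, 48.0 and 68.5%. A cluster of 33 epithelial-like cells led by Epcam had Xist in 18.2% and Y-linked genes in 69.7% of cells.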
